A study of Mus musculus with 7 samples.

How the data were processed

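Brain RNA of 24 months old mice was sequenced in 7 libraries, 4 labelled on and 3 labelled off. Per the labels, RNA was extracted with a Qiagen miRNeasy kit with DNase digestion on the column, and libraries were made with the Illumina TruSeq Stranded mRNA kit, which selects RNA with a poly(A) tail and keeps the strand. The instrument was an Illumina HiSeq, per the series description. The submitters' processing notes name cutadapt 1.9.1, BWA 0.7.14-r1136, STAR 2.5.2, Subread 1.5.3, DESeq2 1.16.1 and the mouse genome build GRCm38, without a role or an order for each. The annotation release, the strand setting of the counting, filters and the options of the transformation are not given in the sources used here.

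The deposited values are regularized logarithms (rlog) on the log2 scale, 1 column per library, for 48526 Ensembl genes. In this transformation DESeq2, named in the submitters' processing notes, divides counts by size factors and shrinks each gene's deviations from its mean, most strongly at low counts. Differences between groups therefore understate the change of low genes. Counts and library totals were not used here, so the depth of each library is unknown and no counting interval is given. Of these genes, 13834 are listed at 0 in every library, and the values run from -2.39 to 19.4. Symbols were found for 48058 of the gene identifiers (99.0%). Positions, transcript lengths and GC content came from GENCODE M21 on GRCm38, which held 48144 of them.

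Genes with a mean deposited value of 3 or more over the 7 libraries were tested, 17896 in all. Differences, on minus off, were fitted with limma 3.58.1 in R 4.3.3, with a group term only, moderated variances with an intensity trend, two-sided tests and Benjamini-Hochberg adjustment, at a threshold of 0.05. Errors of differences are moderated standard errors (SE), and errors of group means are standard deviations (SD). Gene lists, 47 in number, were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists, and again with the correlation estimated for each list and with fry. A list needed 4 tested genes. Tests, lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule named Sncb and Sncg; the 12 largest differences in each direction among called genes with a gene symbol that is not a model number and with on and off libraries that do not overlap; the genes with the smallest p of each list described; markers of glia, dopamine cells, forebrain neurons, myelin and synapses; and sex-linked, blood and choroid plexus genes. Some genes that the rule names are not reported here.

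Alternatives were no filter, a stricter filter at a mean of 5, centring on medians, quantile normalization, limma without the trend, with a robust prior or with array weights, the replicate number as a block, a threshold of 0.1, and each library left out in turn. A correction for GC content and transcript length was chosen after seeing the data. It removed from each library a smooth trend with both properties, fitted with mgcv 1.9.3 in 3 classes of mean value, and 17831 tested genes (99.6%) had both properties. No 2 of the 7 libraries held identical values.

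The methods were tested on simulated data for 17896 genes in the same 4 against 3 design. Of 50 genes changed by 0.2, 44% were recovered, and of 50 changed by 0.4, 88%. All 50 changed by 0.8 and all 50 changed by 1.6 were recovered, and 10 of 176 calls were false. With a simulated length trend, 7635 unchanged genes were called before the correction and 20 after it. Simulated noise was independent between genes, unlike that of the real libraries, so these rates may not hold for the real calls. The simulated trend was also the same in every on library, which the real trend was not.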

Results

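RNA from mouse brain was measured in animals carrying the V1S and SV2 constructs, whose labels name the fluorescent protein Venus. The 4 on libraries carry the label glucose and the 3 off libraries the label Dox, and all come from mice of 24 months. The brain region is not given in the sources used here. Values are rlog values on the log2 scale, and depth per library is unknown. The labels do not say that each library is a separate animal, so p-values measure only the spread between these samples. Doxycycline and the state of the constructs change together in this design, so no comparison separates them.

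The comparison asks which genes differ between brains with the constructs on and off. Of 17896 genes tested, 466 passed the threshold, 146 higher and 320 lower in on. Over all 17896 tested genes, on and off libraries did not overlap in 2724 (15.2%), where chance gives 5.71% on average. Genes vary together across these libraries, so a single grouping can lie far from that average without a group effect. The largest positive difference was that of mt-Nd6, a complex I subunit encoded on the light strand of mitochondrial DNA, at 0.71 ± 0.06 (SE), from 11.05 ± 0.16 (SD, n = 3) to 11.76 ± 0.04 (SD, n = 4). Car4, a membrane-bound carbonic anhydrase, was higher by 0.57 ± 0.07 (SE, adjusted p = 0.00105), the mitochondrial tRNA mt-Tp by 0.46 ± 0.06 (SE, adjusted p = 0.00215) and the basement membrane collagen Col15a1 by 0.39 ± 0.06 (SE, adjusted p = 0.00447). The gene mt-Nd6 lies at 13552 to 14070 on the minus strand of the mitochondrial genome, most of whose abundant transcripts come from the other strand, and the strand setting of the counting is not given in the sources used here. These 4 genes passed with any single library left out. Sncb and Sncg, which encode β-synuclein and γ-synuclein, did not pass, with differences of -0.13 ± 0.05 (SE, adjusted p = 0.137) and 0.00 ± 0.08 (SE, adjusted p = 1). The number of genes called moved widely when 1 library was left out: 2917 without on replicate 1, 175 without on replicate 2, 57 without on replicate 3, 85 without on replicate 4, 43 without off replicate 2 and 74 without off replicate 3. After the GC and length correction 85 genes were called, 71 of them among the 466 and in the same direction.

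**Figure D1:**
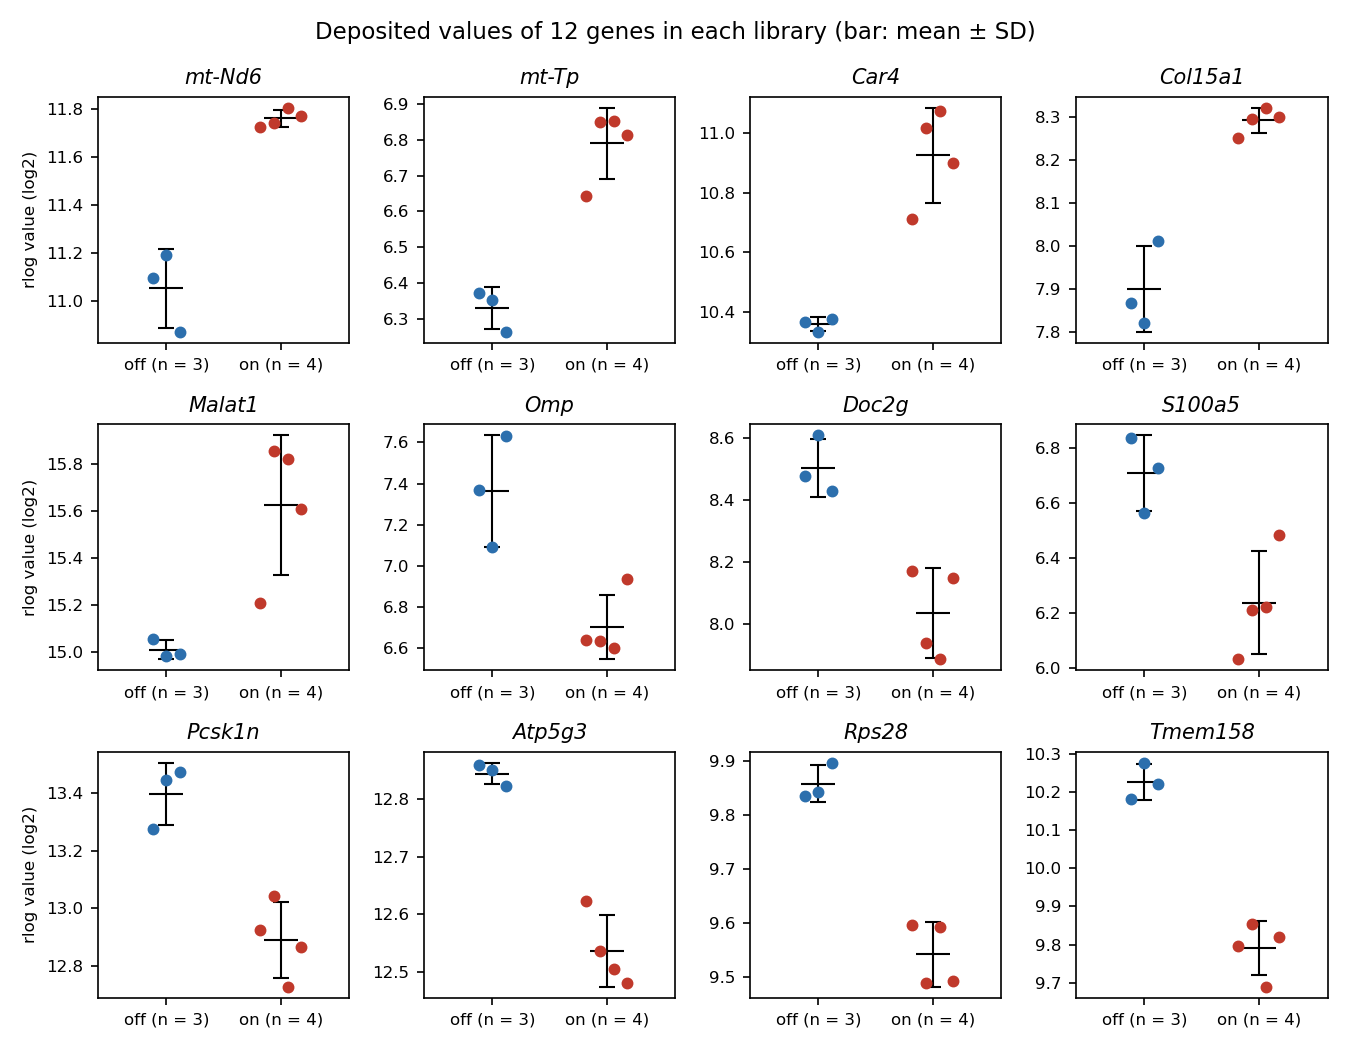
Deposited rlog value (log2 scale) of 12 genes in each library, off (n = 3) and on (n = 4); points are libraries and bars are mean ± SD. The gene mt-Nd6 lies at 11.76 in on and 11.05 in off, with no overlap between the groups.

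Lower in on were Omp, the olfactory marker protein of olfactory sensory neurons, by -0.66 ± 0.11 (SE, adjusted p = 0.00839), and Pcsk1n, which encodes the prohormone convertase inhibitor proSAAS, by -0.51 ± 0.06 (SE, adjusted p = 0.0016). S100a5 differed by -0.47 ± 0.09 (SE, adjusted p = 0.0182) and Doc2g by -0.47 ± 0.07 (SE, adjusted p = 0.00801). The other large negative differences were those of C1qtnf4 (-0.44), Tmem158 (-0.44), Rpl37rt (-0.43), H1fx (-0.42), Scand1 (-0.42), Cebpb (-0.42), Tmem160 (-0.41) and Tmem121 (-0.41). Omp missed the threshold without off replicate 3 (adjusted p = 0.057) and Doc2g without off replicate 2 (adjusted p = 0.069). S100a5 missed it without on replicate 3 (0.068), off replicate 1 (0.061) or off replicate 3 (0.095). Tmem121 missed it without off replicate 2 (0.073) or off replicate 3 (0.068), and Cebpb without on replicate 2 (0.055), on replicate 3 (0.068), on replicate 4 (0.053), off replicate 1 (0.056) or off replicate 3 (0.080). After the GC and length correction 5 of these 12 genes passed: Omp at -0.62 ± 0.11 (SE), Pcsk1n at -0.43 ± 0.06, Doc2g at -0.41 ± 0.07, Rpl37rt at -0.41 ± 0.05 and Tmem158, which was smaller, at -0.27 ± 0.04. Rpl37rt is annotated as a transcribed processed pseudogene, with low means of 4.79 in on and 5.22 in off. Whether its reads are shared with a ribosomal protein gene was not tested, so its value is uncertain. S100a5 kept its difference at -0.45 ± 0.09 (SE) and missed the threshold (adjusted p = 0.0509). The differences of the other 6 were smaller and did not pass: Cebpb -0.33 ± 0.09 (SE), Tmem121 -0.24 ± 0.05, Tmem160 -0.19 ± 0.04, H1fx -0.18 ± 0.07, Scand1 -0.16 ± 0.05 and C1qtnf4 -0.11 ± 0.04.

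Among the other genes higher in on, the nuclear long noncoding RNA Malat1 differed by 0.61 ± 0.11 (SE, adjusted p = 0.0159). The extracellular matrix gene Sned1 differed by 0.41, Ahnak by 0.40, the cytoskeletal linker Dst by 0.34, the histone methyltransferase Kmt2a by 0.33, Stard9 by 0.33 and the transcription factor Zbtb20 by 0.33. Malat1 missed the threshold without on replicate 3 (adjusted p = 0.061), off replicate 2 (0.094) or off replicate 3 (0.091), and only Zbtb20 of the 7 genes passed with any single library left out. Without on replicate 3 the adjusted p was 0.062 for Sned1, 0.052 for Ahnak, 0.069 for Dst, 0.053 for Kmt2a and 0.11 for Stard9, and without off replicate 2 it was 0.099, 0.092, 0.067, 0.089 and 0.16. Ahnak also missed the threshold without off replicate 3 (0.067), Sned1 and Dst without on replicate 4 (0.052 and 0.050), and Stard9 without on replicate 2 (0.065), on replicate 4 (0.094) or off replicate 1 (0.062). After the GC and length correction Malat1 (0.52 ± 0.10, SE) and Sned1 (0.35 ± 0.07, SE) passed. Ahnak (0.21 ± 0.05, SE), Stard9 (0.17 ± 0.05), Kmt2a (0.17 ± 0.04), Dst (0.14 ± 0.06) and Zbtb20 (0.09 ± 0.03) had smaller differences and did not.

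The genes called lower in on had a median transcript length of 1709 bases and a median GC content of 56.9%, against 3158 bases and 49.5% for all tested genes. Those called higher had a median length of 8336 bases. Of the 146 genes called higher, 114 lay in the longest quintile of genes, and of the 320 called lower, 165 lay in the shortest quintile and 189 in the most GC-rich quintile. Across genes, which are not independent replicates, Spearman's rho of the deviation from the gene's mean with transcript length was between 0.274 and 0.291 in on replicates 2, 3 and 4, between -0.316 and -0.233 in the off libraries, and -0.0592 in on replicate 1. On the first principal component, with 47.7% of the variance, on replicate 1 lay at -4.10 among the off libraries (-8.64 to -3.56), and the other on libraries lay between 7.19 and 9.15.

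**Figure D2:**
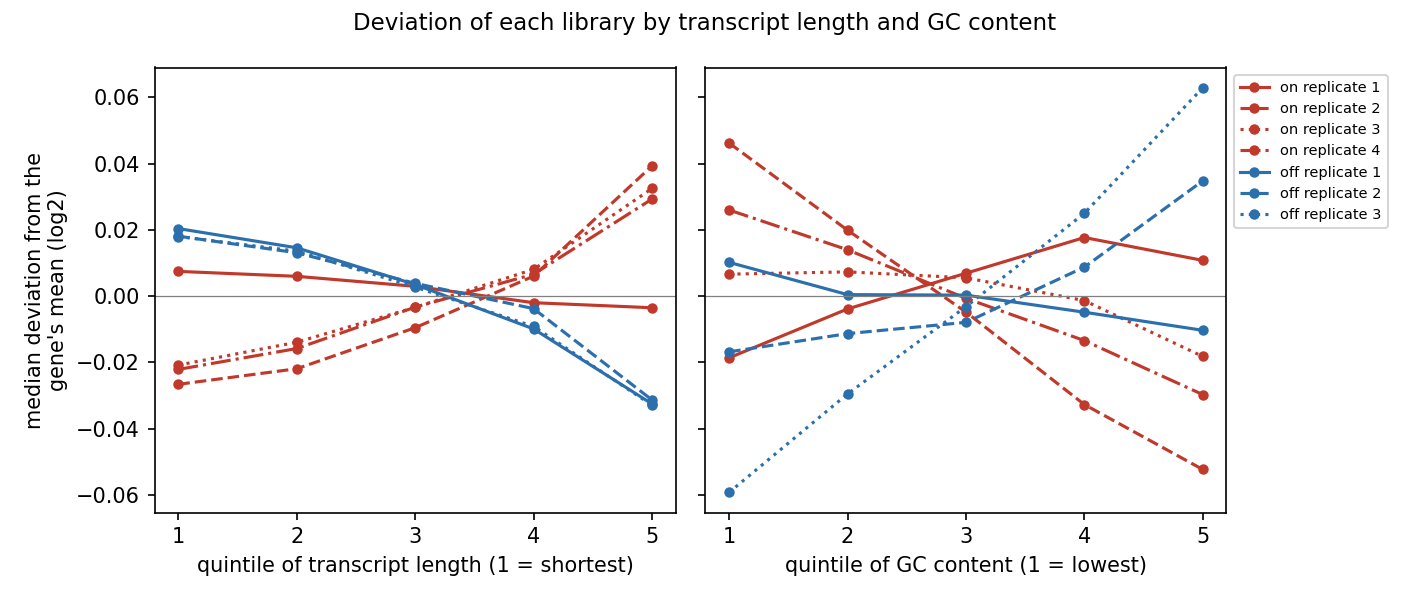
Median deviation of each library from the gene's mean (log2) in quintiles of transcript length (left) and GC content (right); lines are libraries, red for on and blue for off. In the longest quintile on replicate 2 lies at 0.0393 and off replicate 1 at -0.0325, and on replicate 1 at -0.00349.

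**Figure D3:**
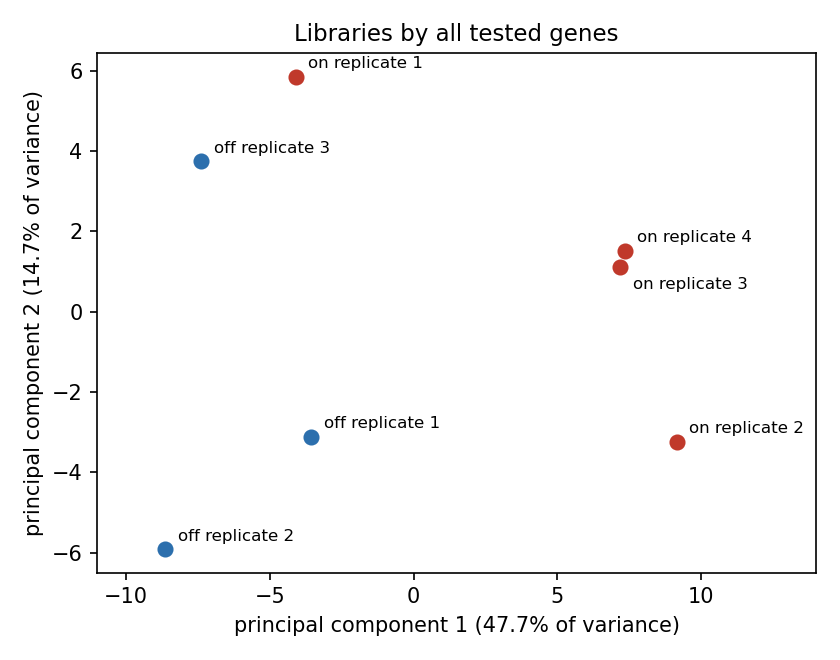
First and second principal component scores of the 7 libraries over all tested genes (47.7% and 14.7% of variance); red points are on and blue points off. On replicate 1, at -4.10, lies with the off libraries on the first component.

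Of the 47 gene lists, 19 passed the preset list test, 14 lower and 5 higher in on. None of the 19 passed with an estimated correlation in limma camera (smallest adjusted p = 0.85 with an estimated correlation, 0 lists at an unadjusted p under 0.05) or with directional fry (smallest adjusted p = 0.25, 6 lists at an unadjusted p under 0.05). The statements on lists that follow carry that limit. The mean deviations of on and off libraries overlapped in 11 of the 19 lists, in each of them through on replicate 1, and in 4 of them, hypothalamus, cerebellum and both microglia lists, through another on library as well.

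Nuclear genes of oxidative phosphorylation were lower in on, with a median of -0.12 over 52 genes, of which 13 passed lower and 39 did not pass over all genes, and 32 passed lower adjusted over the list alone (adjusted p = 4.8e-16, adjusted p = 0.85 with an estimated correlation). Atp5g3, a subunit of ATP synthase, fell by 0.31 ± 0.04 (SE) and Cox5a, a subunit of cytochrome c oxidase, fell by 0.25 ± 0.04 (SE). Cox5a missed the threshold without off replicate 2 (adjusted p = 0.063). Cytoplasmic ribosomal protein genes had a median of -0.13 over 54 genes, of which 8 passed lower and 46 did not, and 23 passed lower adjusted over the list alone (adjusted p = 6.4e-13, adjusted p = 0.85 with an estimated correlation). The mean deviation of the ribosomal list was 0.0756 in on replicate 1, above off replicates 1 (0.0646) and 3 (0.0557), against -0.147 to -0.0592 in the other on libraries and 0.107 in off replicate 2. That of oxidative phosphorylation was 0.0293 in on replicate 1, -0.103 to -0.0614 in the other on libraries and 0.0438 to 0.116 in the off libraries. Rps28 fell by 0.32 ± 0.05 (SE) and Rps16 by 0.33 ± 0.05 (SE); processed copies of ribosomal protein genes elsewhere in the genome share sequence with them, so these values are uncertain. Both lists hold short transcripts, and after the GC and length correction their medians were -0.05 and -0.04, with 5 and 3 genes past the threshold.

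Olfactory bulb genes had a median of -0.19 over 18 genes, 17 of them negative, with a mean deviation of -0.157 and -0.195 in on replicates 2 and 3, of -0.0039 and -0.0022 in on replicates 1 and 4, and of 0.0972 to 0.139 in the off libraries; 3 passed lower and 15 did not, and 8 passed lower adjusted over the list alone (adjusted p = 9.1e-08, adjusted p = 0.85 with an estimated correlation). Th, the rate-limiting enzyme of dopamine synthesis, differed by -0.31 ± 0.07 (SE, adjusted p = 0.0382) and missed the threshold in 6 of the 7 fits without 1 library, all but that without on replicate 1. Markers of the striatum were lower in all 22 genes with a median of -0.14, of which 1, Syndig1l, passed and 21 did not, and 11 passed adjusted over the list alone (adjusted p = 1.8e-07, adjusted p = 0.85 with an estimated correlation). The mean deviation of the striatum list was 0.170 in off replicate 2 and 0.0217 and 0.0223 in off replicates 1 and 3. In on replicates 1 to 4 it was -0.0127, -0.1195, -0.0588 and -0.0234. GABAergic interneuron genes had a median of -0.13 over 20 genes, 3 of which passed lower and 17 did not, and 9 passed lower and 1 higher adjusted over the list alone (adjusted p = 1.4e-05, adjusted p = 0.85 with an estimated correlation). Among them Slc32a1, the vesicular GABA transporter, fell by 0.23 ± 0.05 (SE) and the neuropeptide Sst by 0.29 ± 0.06 (SE), and both missed the threshold in 5 of the 7 fits without 1 library, passing only without on replicate 1 or off replicate 1. Syndig1l missed it in 6 of the 7 fits, all but that without on replicate 1. The mean deviation of the interneuron list was 0.141 in off replicate 2 and 0.0441 and 0.0375 in off replicates 1 and 3. In on replicates 1 to 4 it was 0.0023, -0.0848, -0.111 and -0.0297. After the GC and length correction Th (-0.25 ± 0.07, SE), Syndig1l (-0.12 ± 0.04), Slc32a1 (-0.13 ± 0.03) and Sst (-0.16 ± 0.05) did not pass.

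Nuclear and intronic RNA, a list of signs of RNA quality, was higher in on with a median of 0.19 over 11 genes, of which 2, Malat1 and Snhg14, passed and 9 did not, and 5 passed adjusted over the list alone (adjusted p = 0.00022, adjusted p = 0.85 with an estimated correlation). Its mean deviation was -0.092 in on replicate 1 and between 0.121 and 0.170 in the other on libraries. After the GC and length correction the median was 0.07 (adjusted p = 0.28). Snhg14 missed the threshold without on replicate 3 (adjusted p = 0.056), off replicate 2 (0.091) or off replicate 3 (0.079). It did not pass after the correction (0.13 ± 0.04, SE, adjusted p = 0.109).

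Glial markers gave few calls. Gfap, the intermediate filament of astrocytes, differed by -0.04 ± 0.08 (SE, adjusted p = 0.81), Aif1 by -0.09 ± 0.07 (SE, adjusted p = 0.46), Tyrobp by -0.14 ± 0.08 (SE, adjusted p = 0.337), C1qa by -0.05 ± 0.07 (SE, adjusted p = 0.72) and the microglial receptor gene Trem2 by -0.23 ± 0.07 (SE, adjusted p = 0.0914). Gfap and C1qa had the opposite sign after the GC and length correction. Homeostatic microglia genes had a median of -0.07 over 17 genes and disease-associated microglia genes of -0.05 over 23 genes, with 0 genes past the limma threshold in either, 0 adjusted over the list alone, and 3 and 5 at an unadjusted p under 0.05 (adjusted p = 0.028 and 0.047, adjusted p = 0.85 with an estimated correlation for both). The synaptic vesicle gene Syp (-0.05 ± 0.05, SE), the kinase gene Camk2a (-0.05 ± 0.05, SE) and the myelin gene Mbp (-0.05 ± 0.07, SE) did not pass, with adjusted p of 0.628, 0.635 and 0.698.

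**Figure D4:**
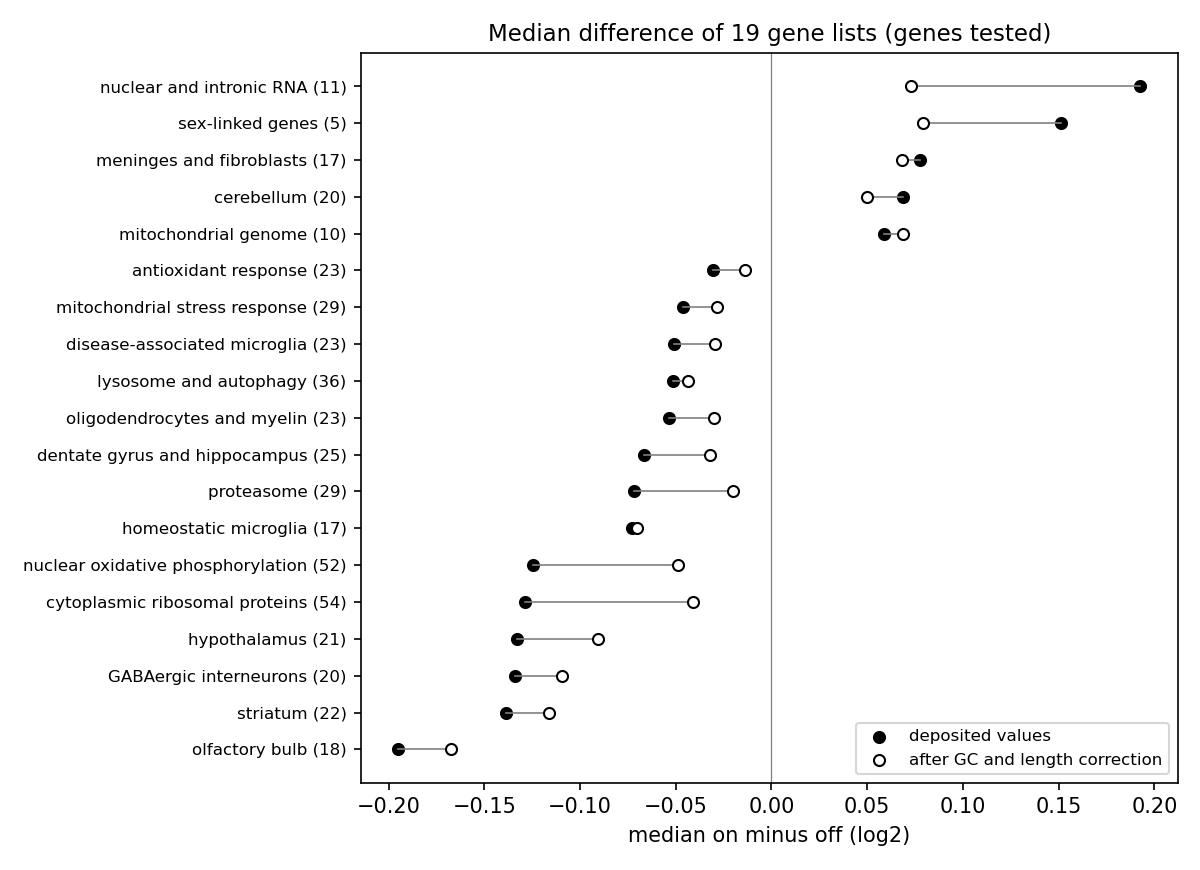
Median on minus off difference (log2) of the gene lists that passed the preset list test, with the number of genes tested in brackets; filled points are deposited values and open points are values after the GC and length correction. The median for nuclear oxidative phosphorylation moves from -0.12 to -0.05 and that for olfactory bulb from -0.19 to -0.17.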

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

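The GC and length correction and the test of RNAs without a poly(A) tail were chosen after the data were seen, as were the minimum abundance set for genes in the tests on mt-Nd6 and the use of the length trend per library to test on replicate 1 alone. A gap test of the 4 on libraries over 64 values gave 8 with 1 library far from the others, where chance gives about 3.2, since it singles out about 1 in 20 such groups. On replicate 1 lay at -4.10 on the first principal component against 7.19 to 9.15 in the other on libraries, and its rho with transcript length was -0.0592 against 0.274 to 0.291. It also lay apart in Sned1 (10.23 against 10.52 to 10.56), Trem2 (8.87 against 8.62 to 8.64), Kdm5d (10.02 against 10.20 to 10.22) and the mean deviation of antioxidant response genes (0.0462 against -0.0536 to -0.0433). On replicate 4 lay apart in Omp, at 6.94 against 6.60 to 6.64. On replicate 3 had the lowest mean deviation of the mitochondrial genome list, 0.0265 against 0.0515 to 0.0556.

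Short, GC-rich genes were lower and long genes higher in on. On replicate 1 alone is argued against, since rho with transcript length was 0.274 to 0.291 in the other on libraries, -0.0592 in on replicate 1 and -0.316 to -0.233 in the off libraries; 100% of the 466 calls held without it, though this adds little, because 399 of the differences were then larger and 67 smaller. After removal of each library's trend with GC content and transcript length, 15.2% of the called genes stayed past the threshold in the same direction, between the bounds of under 10% and of 50% set in advance, so this trend may account for part of the calls. A technical trend and a change that falls on short or long genes cannot be told apart here, because the trend with length runs along the groups in 6 of the 7 libraries. A difference between on and off brains stays open and was not tested.

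The values of mt-Nd6 and mt-Tp were higher in on. The trend with GC content and transcript length is argued against, since mt-Nd6 kept 0.753 ± 0.049 (SE) after the correction. Reads from the opposite strand stay open. Of the nuclear genes lying mostly opposite a gene at least 4 log2 units more abundant, 10 were as abundant as mt-Tp. Their median was -0.0252 ± 0.0214 (bootstrap error over genes). That cannot decide, because 10 genes are few and the share of their reads from the opposite strand is unknown. More RNA without a poly(A) tail in the on libraries cannot be told apart from a change in these genes. Only 3 genes of that test set, the histone genes Hist1h2bc, Hist1h1c and Hist3h2a, were as abundant as mt-Tp (median -0.0472). Whether their reads lack a poly(A) tail was not measured. Over all 73 RNAs of the set the median was 0.0171 ± 0.00624 (bootstrap error over genes) with 0 called higher by limma. That counted as excluding this explanation until the minimum abundance was added for the shrinkage of low values. An effect of the constructs or of doxycycline stays open and was not tested.

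Olfactory bulb genes were lower in on. The trend with GC content and transcript length is argued against as the whole cause, since the list's median was -0.168 after the correction. Its bootstrap error of 0.0325 is over the 18 genes, which share the same libraries, and does not measure the spread between libraries. With an estimated correlation in limma camera the corrected list had an adjusted p of 0.85, so the remaining difference is uncertain. Less olfactory bulb tissue in the on libraries stays open: 17 of the 18 genes were lower after the correction, but 17 were lower before it too, and the other part of that test used Omp, Doc2g and S100a5, picked after their differences were seen, so neither part decides. The bulb is not alone, since the striatum and hypothalamus lists also had negative medians after the correction (-0.12 and -0.09), and 7 of the 18 genes are also in other lists. A change of these genes within the bulb was not tested, and the brain region is not given.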

How the results depend on the processing

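The GC and length correction, alone or combined, was chosen after the data were seen. The count of genes called, 466 (146 higher, 320 lower), was 7 (2 and 5) with no filter, 237 (57 and 180) without the intensity trend, 2215 (1081 and 1134) with array weights, 1182 (455 and 727) at a threshold of 0.1, 85 (16 and 69) after the GC and length correction and 1846 (869 and 977) after it with on replicate 1 left out. With 1 library left out it ran from 43 to 2917 (6 to 1481 higher, 37 to 1436 lower). Under the stricter filter, centring, quantile normalization and the robust prior it was 458, 424, 424 and 539. The cause was not tested. No filter nearly doubles the genes tested, to 34692. That alone cannot account for the fall to 7 calls, because at unchanged p it can at most about double an adjusted p. The numbers of the replicates do not pair the libraries: deviations of same-numbered libraries correlated at -0.228, -0.1 and 0.0176. With the replicate block 30 genes were called (6 and 24), and 17 (6 and 11) with the block and the GC and length correction. Of the 35 splits of the libraries into 4 and 3, 2 called 466 genes or more, the real split included, so chance cannot be excluded at 0.05. The highest other split, on replicate 1 with the 3 off libraries, called 3083. That split differs from the labels only in on replicate 1, and the labelled fit without this library called 2917. For the lists, 22 splits, the real one included, called 19 or more and the highest other called 27, so chance cannot be excluded. The count of lists was 0 with estimated correlations, 0 with directional fry, 12 with mixed fry and 14 to 25 under the other alternatives. Mixed fry tests no direction, and only 6 of its 12 lists were among the 19. Genes that did not pass and changed sign were Sncg (-0.033 with array weights, -0.0757 to 0.0576 with 1 library left out), Gfap (0.0394 with the replicate block, -0.126 to 0.0394 with 1 left out, 0.0053 after the GC and length correction), C1qa (-0.13 to 0.0012 with 1 left out, 0.0806 after the correction), Ttr (-0.13 to 0.0034 with 1 left out, 0.0071 after the correction), Camk2a (-0.0854 to 0.0029 with 1 left out), Xist (-0.11 after the correction) and Sncb (0.0122 after the correction). Depth is unknown, and shrinkage at low counts limits what low genes can show.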

Other observations

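Lists of other brain regions and processes also passed the preset list test, each with an adjusted p of 0.85 with an estimated correlation. Hypothalamus genes had a median of -0.13 over 21 genes (0 passed by limma, 7 at an unadjusted p under 0.05, 2 lower adjusted over the list alone), with a mean deviation of 0.171 in on replicate 1, above off replicate 1 (0.148), and of -0.105 in off replicate 2, below on replicate 4 (-0.0889); on replicates 2 and 3 lay at -0.134 and -0.221 and off replicate 3 at 0.230. Proteasome genes had a median of -0.07 over 29 genes (0 passed by limma, 10 at an unadjusted p under 0.05, 6 lower adjusted over the list alone). Dentate gyrus and hippocampus genes had 3 of 25 lower and 1 higher, led by C1ql2 (-0.36 ± 0.06, SE) and Zbtb20. Lysosome and autophagy genes had a median of -0.05 over 36 genes with 1 lower, Map1lc3a, the autophagosome protein LC3A (-0.28 ± 0.04, SE). Mitochondrial stress response and antioxidant response genes had 2 of 29 and 2 of 23 lower, among them the serine synthesis enzyme Phgdh (-0.27 ± 0.06, SE) and the metallothionein Mt3 (-0.34 ± 0.05, SE). Higher in on were meninges and fibroblasts, with a median of 0.08 over 17 genes, 1 higher (Fn1, fibronectin, 0.29 ± 0.06, SE) and 1 lower (Igfbp2, -0.21 ± 0.05, SE), and cerebellum, with a median of 0.07 over 20 genes (0 passed by limma, 5 at an unadjusted p under 0.05, 1 higher adjusted over the list alone). When 1 library was left out, Phgdh and Fn1 missed the threshold in 6 of the 7 fits, Igfbp2 in 5, C1ql2 in 3 and Mt3 in 2, and Map1lc3a without off replicate 2 (adjusted p = 0.06). After the GC and length correction none of these 6 passed: Fn1 was at 0.22 ± 0.05 (SE, adjusted p = 0.0733), Phgdh at -0.20 ± 0.05 (SE, 0.0733), C1ql2 at -0.21 ± 0.05 (SE, 0.0838), Mt3 at -0.14 ± 0.04 (SE, 0.109), Map1lc3a at -0.10 ± 0.03 (SE, 0.16) and Igfbp2 at -0.05 ± 0.04 (SE, 0.511). After the correction 20 lists passed the preset test, 12 of the 19 and 8 that had not passed on the deposited values, none of them with an estimated correlation (adjusted p of 0.70 or more with an estimated correlation). Among the 8 were, lower, presynaptic vesicle and SNARE (median -0.05, adjusted p = 0.00067), excitatory forebrain neurons (-0.06, 0.012), oligodendrocyte precursors (-0.05, 0.014) and postsynaptic density and glutamate receptors (-0.04, 0.024), and, higher, immediate early genes (0.10, 0.0096), pericytes and vascular smooth muscle (0.10, 0.0096) and glucocorticoid response (0.07, 0.024). The 7 of the 19 that did not pass were proteasome (median -0.02, adjusted p = 0.11), oligodendrocytes and myelin (0.14), sex-linked genes (0.14), mitochondrial stress response (0.21), disease-associated microglia (0.23), antioxidant response (0.24) and nuclear and intronic RNA (0.28). The 28 lists outside the 19 did not pass on the deposited values, and 20 of them passed neither before nor after the correction.

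Mitochondrial genes are given by strand, a grouping chosen after their values were seen. Of 5 light-strand genes 3 passed higher in on, mt-Nd6, mt-Tp and mt-Tq (0.27 ± 0.07, SE, adjusted p = 0.0493), with values from -0.01 to 0.71, and mt-Tq did not pass after the GC and length correction (0.24, adjusted p = 0.121). Of 7 heavy-strand protein-coding genes, from -0.11 to 0.14, 0 passed higher and 1, mt-Nd3, passed lower by limma, which it did not in 6 of the 7 fits without 1 library. The mean of mt-Nd3 was 3.49 in on and 3.60 in off, near the filter at 3. Its neighbours among the tested protein-coding genes lay far higher, mt-Co1 at 19.30 and mt-Nd4 at 17.05 in on. Why mt-Nd3 was so low was not tested, so its value is uncertain. After the GC and length correction mt-Nd3 did not pass (-0.13, adjusted p = 0.124). Of the 15 genes in the mitochondrial genome list, 10 were tested. The heavy-strand tRNAs did not pass, with mt-Tm at -0.19 (adjusted p = 0.075), mt-Tt at -0.18 (0.0844), mt-Ti at 0.01 (0.941) and mt-Tw at 0.21 (0.178). The mitochondrial genome list, 9 of its 10 tested genes positive, passed the preset list test higher (median 0.06, adjusted p = 0.038, adjusted p = 0.85 with an estimated correlation; 0.00026 and 0.70 after the correction), with 1 gene higher and 1 lower, over all genes and adjusted over the list alone. The 2 rRNAs, mt-Rnr1 and mt-Rnr2, differed by 0.003 and 0.016.

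Xist, expressed from the inactive X chromosome, lay between 8.59 and 8.85 in all 7 libraries, and the Y-linked gene Ddx3y between 10.90 and 11.25 in the same libraries. The sex-linked list had 5 tested genes, all positive, with a median of 0.15. It passed the preset list test higher (adjusted p = 0.0087, 0.85 with an estimated correlation), but not after the GC and length correction (0.14). Of the 5, 1 passed by limma and 4 adjusted over the list alone. Ddx3y (0.16 ± 0.06, SE), Eif2s3y (0.15 ± 0.06) and Uty (0.14 ± 0.06) did not pass (adjusted p = 0.153, 0.172 and 0.185). The sex of the animals is not given in the sources used here. Kdm5d differed by 0.24 ± 0.06 (SE, adjusted p = 0.0441), missed the threshold in 6 of the 7 fits without 1 library, and differed by 0.15 after the GC and length correction (adjusted p = 0.14). The hemoglobin gene Hbb-bs differed by -0.24 ± 0.18 (SE, adjusted p = 0.477) and Ttr, abundant in choroid plexus, by -0.05 ± 0.07 (SE, adjusted p = 0.722).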
